A study of Bifidobacterium breve UCC2003 with 8 samples.

How the data were processed

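RNA from 4 mutants and the wild type of *B. breve* UCC2003 was compared on 8 2-colour Agilent arrays, 2 per mutant with the dyes exchanged. The deposited scanner files give intensity values for each spot, namely median pixel signals, local background and processed signals, per the file headers. The scanner software also wrote log10 ratios of the processed Cy5 over Cy3 signals per the file headers, and the deposited series table holds these same log10 ratios in every spot (largest difference 0). Other columns hold flags of 0 or 1 set for each spot and channel by the scanner software, per the file headers. The submitters' notes name Agilent Feature Extraction 9.5, whereas the file headers name other versions for the arrays of slide 1 and for those of slides 2 and 3. The labels name Cyber-T with p under 0.001 and a ratio above 3 or below 0.33.

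The design had named mean signals. The malR2 and malR5 files give median signals instead, so median signals were used on all arrays. They were background corrected with normexp (offset 50) and normalised by loess within arrays in limma 3.58.1 (R 4.3.3), with control spots at weight 0. Spots marked as non-uniform or population outliers were left out. Spots of a probe were averaged, then probes of a locus. A locus was tested when a probe was above background in at least 1 channel on at least 2 arrays; all 1843 passed.

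A linear model was fitted to the log2 ratios of all 8 arrays in limma, with 1 coefficient per mutant and 1 dye effect common to all arrays, which leaves 3 residual degrees of freedom. Two-sided p-values were adjusted by Benjamini-Hochberg within each mutant or pair of mutants, and loci were called at an adjusted p under 0.05. A 3-fold threshold was applied to the called loci as a separate count. The 6 pairs of mutants were compared by contrasts in the same model. Shared calls were set beside the number expected of independent calls, with Fisher's exact test as a description across loci. A run is at least 3 loci called in the same direction whose tag numbers follow with gaps of at most 2, and runs were tested with 10000 shuffles.

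Single loci were chosen by a rule written before the data were examined: the 10 largest rises and 10 largest falls per mutant with the same direction on both arrays, the ends of the 5 longest runs, and up to 5 loci changed alike in all 4 mutants. Its parts on gene lists and on annotated regulators were void, since 22 gene lists fixed beforehand rested on product names and 0 could be built. Because the files pair no names with the tags, only a few of these loci are printed. The 12 regions and the loci with protein motifs were chosen after the values were seen. Probes were translated in all frames with Biopython 1.88 and searched for 12 motifs; 2 of them, the LacI-type DNA-binding helix and the binding-protein-dependent permease, matched 0 loci, and in shuffled sequences only the alpha-amylase motif matched, at 1 locus against 5.

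The steps after averaging over probes were tested on simulated locus values with the spread and dye effect of the 1843 real loci. Background correction, loess and averaging over probes were not simulated. Of 50 loci changed by a log2 ratio of 1 in the simulated malR2 comparison 100% were recovered with the right sign, and of 50 changed by 0.5 92% were. The share of unchanged loci among its calls was 3.92%. The simulated noise was independent and most loci were unchanged, whereas 54.2% to 64.6% of real loci were called. This share therefore does not carry over to the real calls.

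Alternatives fixed before the data were examined were no background correction, the processed signals, the series table, median centring, the median over probes, no filter and a strict filter on dim loci, outlier spots kept, no dye effect, a dye effect per slide, each mutant's own arrays, Cyber-T (prior weight 10, window 101), other run gaps and leaving out each array. Chosen after seeing the data were a model without the malR6 arrays, slide 1 alone, and no background correction together with median centring. Tests of gene lists were left out because no list could be built.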

Results

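Transcript levels of *Bifidobacterium breve* UCC2003, a bacterium of the infant gut, were measured on 2-colour oligonucleotide arrays. Mutants of malR2, malR3, malR5 and malR6 were each compared with the wild type on 2 arrays with the dyes exchanged, which makes 8 arrays on 3 slides; the malR2 and malR5 arrays share slide 1, the malR3 arrays lie on slide 2 and the malR6 arrays on slide 3. The series title places the genes in a MalR regulon and names malto-oligosaccharides, short glucose chains released from starch and glycogen. The source names give growth on 1% ribose with 0.05% cysteine, whereas the growth protocol, which names another mutant, gives 0.5% ribose and harvest at an optical density of 0.5. Each array carried 43803 spots for 8262 probes, with a median of 3 probes per locus, and all 1843 loci were tested. Median spot signals ran from 264 to 7464 in the red channel over local backgrounds of 34 to 39.5, and the share of spots above background was lowest at 83.5%. The number of arrays limits the precision. The labels do not say whether the arrays of a pair come from separate cultures, so the p-values measure the spread between arrays, which may be technical; if a pair is 1 pair of extracts, each mutant has a single replicate and no test.

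The files identify loci by tag and pair them with no gene name or product, and 0 of the 1843 tags matched the 2016 genes of the reference table, which covers another strain (assembly ASM102517v1). Changes are therefore given by chromosomal region, from first to last tag, in 12 regions chosen after the values were seen. Some loci are also described by a protein family motif found in their translated probes; these motifs were written after the probes of changed loci had been read, so they identify loci and are no independent evidence. Ratios are log2 of mutant over wild type, with the SD over the 2 arrays for region means and the standard error for single loci; adjusted p-values come from limma.

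In the malR2 mutant the largest rise was in Bbr_1655 to Bbr_1658, whose 4 loci had a mean log2 ratio of 6.30 ± 0.93 (SD, n = 2 arrays). Bbr_1658 was at 6.94 (SE 0.42, adjusted p = 0.000113), with 7.91 and 5.96 on its 2 arrays, 7.83 with processed signals and 5.91 with neither background correction nor loess, a setting chosen after seeing the data. A probe of Bbr_1655 carries the motif of glycoside hydrolase family 1, enzymes that cleave beta-linked sugars. All 11 loci of Bbr_1421 to Bbr_1431 rose, by 2.61 ± 0.03 (SD, n = 2) on the log2 scale; Bbr_1428 and Bbr_1429 within it carry a motif of the ATP-binding subunits of energy-coupling factor transporters, which import vitamins and metals. All 7 measured loci of Bbr_0164 to Bbr_0171 rose by 2.07 ± 0.04 (SD, n = 2), among them Bbr_0166 with a motif of oligopeptide transporter ATPases, and both loci of Bbr_0284 to Bbr_0285 rose by 2.53 ± 0.03 (SD, n = 2). The 4 loci of Bbr_0106 to Bbr_0109 rose by 1.43 ± 0.03 (SD, n = 2) and the 3 of Bbr_1694 to Bbr_1696 by 1.40 ± 0.04 (SD, n = 2).

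The deepest falls in this mutant were in Bbr_1891 to Bbr_1894, with a mean log2 ratio of -5.57 ± 1.01 (SD, n = 2) and a value of -6.65 (SE 0.34, adjusted p = 5.71e-05) for Bbr_1894, or -5.93 and -7.36 on its 2 arrays and -8.86 with processed signals. The 5 loci of Bbr_1843 to Bbr_1847 had a mean of -3.05 ± 0.63 (SD, n = 2); the lowest, Bbr_1847 at -5.20 (adjusted p = 0.000227; -3.94 and -6.46 on its 2 arrays), has probes that share 20-base stretches with those of Bbr_0021 and Bbr_0033. All 8 loci of Bbr_0116 to Bbr_0123 fell, with a mean of -2.48 ± 0.25 (SD, n = 2). That last region holds loci with motifs of alpha-glucan enzymes: Bbr_0123, with the first conserved region of the alpha-amylase family, at -3.07 (adjusted p = 6.80e-06) and Bbr_0116, with a 4-alpha-glucanotransferase motif, at -2.35 (adjusted p = 1.50e-05). Bbr_0060, elsewhere on the chromosome, carries a motif of alpha-glucan phosphorylase, which releases glucose phosphate from glycogen and maltodextrins, and fell to -2.58 (adjusted p = 2.78e-05); its probes share 20-base stretches with those of Bbr_0845. Across the genome 999 of 1843 loci were called, 510 higher and 489 lower, but 941 of them by under 2-fold; 10 of the 20 tested names of plasmid and RNA spike probes, dimmer than most loci and outside those compared, were called too, all lower, and the 20 ran from -0.80 to 0.016. Over 3-fold were 41 loci, 26 higher and 15 lower, each in the same direction on both arrays. With either malR2 array left out, 378 and 323 loci were called in all, while 41 and 40 stayed over 3-fold.

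Changes over 3-fold in the malR5 mutant lay largely in the same regions. Bbr_1655 to Bbr_1658 rose by 6.64 ± 1.30 (SD, n = 2), with Bbr_1658 at 7.11 (SE 0.42, adjusted p = 9.55e-05; 8.19 and 6.03 on its 2 arrays, 8.66 with processed signals), and Bbr_1891 to Bbr_1894 had a mean of -6.10 ± 0.99 (SD, n = 2), with Bbr_1894 at -7.31 (SE 0.34, adjusted p = 4.18e-05; -6.46 and -8.15 on its 2 arrays, -8.99 with processed signals). Bbr_1421 to Bbr_1431 rose by 2.53 ± 0.16 (SD, n = 2), Bbr_0284 to Bbr_0285 by 2.34 ± 0.12 (SD, n = 2) and Bbr_0164 to Bbr_0171 by 1.76 ± 0.02 (SD, n = 2). Means were 1.31 ± 0.13 (SD, n = 2) in Bbr_0106 to Bbr_0109 and 1.32 ± 0.16 (SD, n = 2) in Bbr_1694 to Bbr_1696. The region Bbr_0116 to Bbr_0123 fell in all 8 loci, with a mean of -2.96 ± 0.03 (SD, n = 2), and Bbr_1843 to Bbr_1847 in all 5, with -3.00 ± 0.30 (SD, n = 2). Bbr_0060 was at -2.21 (adjusted p = 5.38e-05).

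Some regions differed between the malR5 and malR2 mutants. All 4 loci of Bbr_1898 to Bbr_1901 fell there, with a mean of -1.03 ± 0.03 (SD, n = 2), against 0.35 ± 0.03 (SD, n = 2) in the malR2 mutant, and all 4 differed between these mutants (largest adjusted p = 0.000520); the malR2 mean was 0.15 with median centring. In Bbr_0445 to Bbr_0448 0 of 4 loci were called in the malR5 mutant (mean -0.04 ± 0.14, SD, n = 2), whereas all 4 were lower in the malR2 mutant (-0.57 ± 0.05, SD, n = 2) and all 4 differed from it (largest adjusted p = 0.0276). The malR5 mutant also differed there in all 4 loci from the malR3 mutant (largest adjusted p = 0.000275) and from malR6 as labelled (0.0437). With median centring the malR5 and malR2 means were -0.28 and -0.27. Genome-wide 1152 loci were called in the malR5 mutant, 617 higher and 535 lower, 1091 of them by under 2-fold; all 20 plasmid and spike names were called higher too, at 0.24 to 0.52. Over 3-fold were 40 loci, 24 higher and 16 lower; one of the latter, Bbr_0461, was not above background in the mutant and was at least 2.90-fold lower, so that its place past 3-fold is not settled. Without malR5 replicate 1 the calls numbered 449, and 39 loci stayed over 3-fold.

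**Figure D1:**
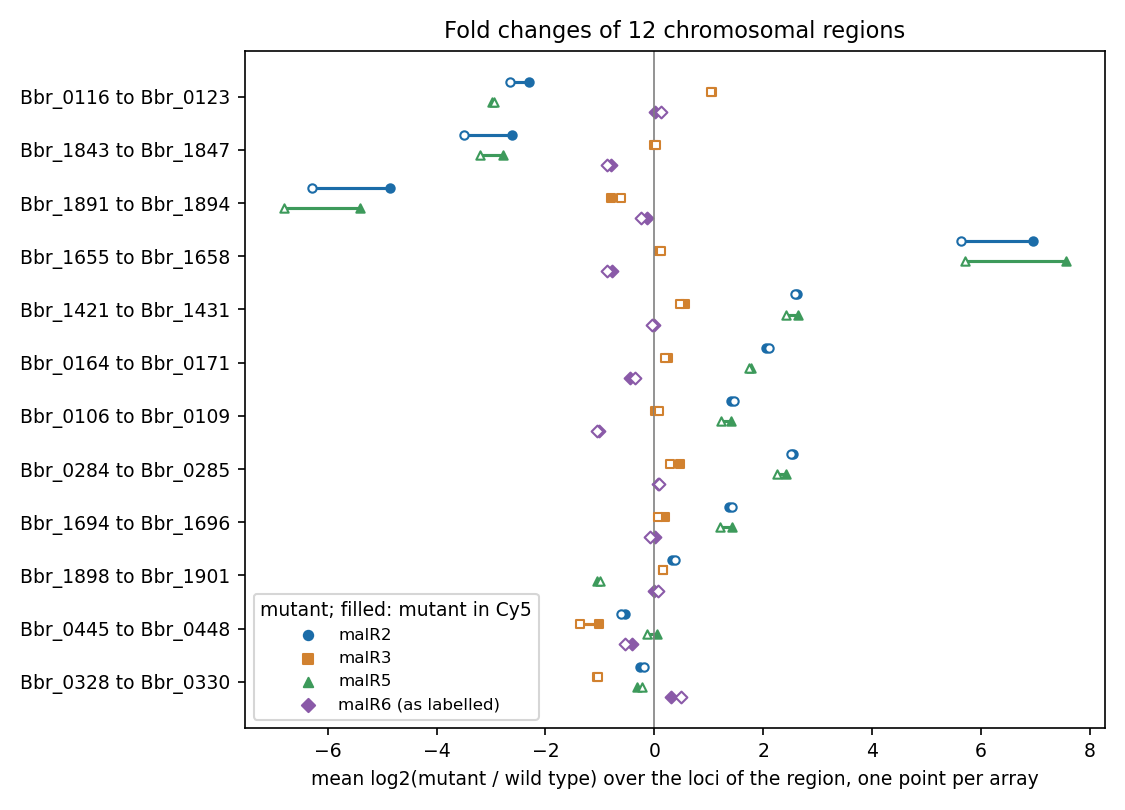
Mean log2 ratio of mutant over wild type (x axis) over the loci of 12 chromosomal regions (y axis), with 1 point per array and a line joining the 2 arrays of a mutant. Filled points have the mutant labelled with Cy5 and open points with Cy3; the malR2 and malR5 points lie together in most regions, and in Bbr_0116 to Bbr_0123 the malR3 points, near 1.05, lie on the other side of 0.

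**Figure D2:**
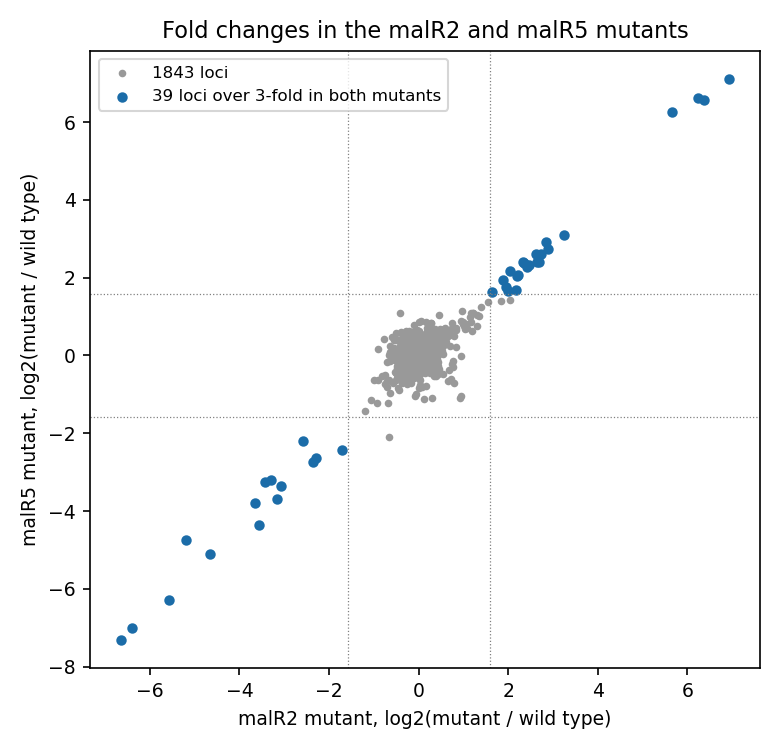
Log2 ratio of mutant over wild type in the malR2 mutant (x axis) and the malR5 mutant (y axis), 1 point per locus for 1843 loci, with dotted lines at 3-fold. The 39 loci beyond 3-fold in both mutants (blue) all changed in the same direction in both.

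The malR3 mutant showed smaller changes, and some ran against those of the other mutants. All 8 loci of Bbr_0116 to Bbr_0123 rose, by a mean of 1.05 ± 0.02 (SD, n = 2), where they had fallen in the malR2 and malR5 mutants; Bbr_0117 was at 1.46 (SE 0.10, adjusted p = 0.000136), Bbr_0123 at 0.94 (adjusted p = 0.000420) and Bbr_0116 at 0.65 (adjusted p = 0.00128). Bbr_0060, with the phosphorylase motif, rose by 0.69 (adjusted p = 0.00275), a call that median centring ended (0.43, adjusted p = 0.0575). Of the 11 loci of Bbr_1421 to Bbr_1431, 10 rose and 1 fell, with a mean of 0.52 ± 0.06 (SD, n = 2). The largest single rise was that of Bbr_1601, at 1.53 (SE 0.08, adjusted p = 6.82e-05).

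Falls in the malR3 mutant included all 4 loci of Bbr_0445 to Bbr_0448, with a mean of -1.19 ± 0.24 (SD, n = 2), and all 3 of Bbr_0328 to Bbr_0330, with -1.04 ± 0.01 (SD, n = 2). The 2 loci past 3-fold both fell, Bbr_1898 to -1.88 (SE 0.05, adjusted p = 3.40e-05) and Bbr_0366 to -1.73 (SE 0.09, adjusted p = 6.82e-05). Of its neighbours, Bbr_1900 rose by 1.24 (adjusted p = 3.57e-05), as did Bbr_1901, which carries a glutaredoxin motif, at 1.28 (adjusted p = 3.40e-05). The called loci numbered 1148, with 581 higher and 567 lower, and 1121 were under 2-fold; 14 of the 20 plasmid and spike names were called lower too, and the 20 ran from -0.31 to -0.15. The number over 3-fold depended on the signal used: the scanner software's processed signals gave 20 in place of 2, with Bbr_0366 at -2.82. The mean of Bbr_0445 to Bbr_0448 ran from -2.38 with the series table to -0.65 with median centring and no background correction, a setting chosen after seeing the data, with all 4 loci lower in each.

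On the malR6 arrays the direction of change follows the labels, which a marker contradicts. Probes for TetW, a tetracycline resistance gene that is no part of the 1843 loci, were 6.11 to 78.8 times brighter in the mutant channel on the 6 arrays of the other mutants. On the malR6 arrays they were 67.9 and 91.2 times brighter in the channel labelled wild type. If the channels are named the wrong way round, every malR6 sign below turns.

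As labelled, the 4 loci of Bbr_0106 to Bbr_0109 had a mean log2 ratio of -1.04 ± 0.03 (SD, n = 2) and all 4 were called lower. Lower values were also called for 6 of 7 loci of Bbr_0164 to Bbr_0171, with a mean of -0.39 ± 0.06 (SD, n = 2), and for all 4 of Bbr_0445 to Bbr_0448, with -0.47 ± 0.09 (SD, n = 2). Over 3-fold were 8 loci, all lower, with Bbr_0433 at -4.84 (SE 0.54, adjusted p = 0.000668; -6.32 and -3.36 on its 2 arrays) and Bbr_1846 at -2.80 (SE 0.11, adjusted p = 7.02e-05). The largest rises were those of Bbr_1619, at 1.23 (SE 0.23, adjusted p = 0.00476; 2.09 and 0.37 on its 2 arrays), and Bbr_0631, at 1.20 (SE 0.05, adjusted p = 7.02e-05). A run of 31 called loci from Bbr_0894 to Bbr_0927 was higher, with a median of 0.40, and a run of 20 from Bbr_0093 to Bbr_0112 was lower, with a median of -0.45. In all 1190 loci were called, 570 higher and 620 lower, 1161 of them by under 2-fold. Of the 20 plasmid and spike names 2 were called higher, and the 20 ran from 0.016 to 0.18. Called loci beyond the largest plasmid or spike value of their mutant were counted, a count chosen after seeing the data. They numbered 73 in malR2, 538 in malR3 and 162 in malR5, so a smaller call is not by itself evidence of a change in transcript level. On the malR6 arrays the count was 905, but these probes set no scale there. Their signals, at a median log2 of 7.07 and 7.21, lay below the fitted backgrounds, which averaged 720 to 5493 before taking logs. Background correction therefore held their ratios near 0.

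Sizes on these arrays depended on the processing. With median centring in place of loess Bbr_0433 was at -1.49, Bbr_1846 at -2.13 and Bbr_1619 at 3.44, and 96 loci passed 3-fold, 95 of them higher. Without background correction, with processed signals or with the series table only 2 loci passed 3-fold, both lower. With median centring and no background correction Bbr_0433 was at -0.45 and was no longer called (adjusted p = 0.0832), nor were Bbr_0107, Bbr_0302 and Bbr_0312 among the 8, and Bbr_1846 was at -1.24. Without malR6 replicate 1 Bbr_1619 was no longer called. Of the runs, that from Bbr_0093 to Bbr_0112 had 11 loci lower and 1 higher with median centring (median -0.20) and 5 lower without background correction as well (-0.21), where that from Bbr_0894 to Bbr_0927 had 16 higher. Bbr_0164 to Bbr_0171 had 3 loci lower with median centring (mean -0.14), and Bbr_0106 to Bbr_0109 had 2 lower without background correction as well (mean -0.58). Under median centring the mean of Bbr_1843 to Bbr_1847 turned from -0.83 to 0.28 and that of Bbr_1891 to Bbr_1894 from -0.19 to 0.90. The malR6 arrays also had a narrow signal range: the SD of log2 signal over loci was 0.45 and 0.56, against 1.32 to 1.49 on the other arrays. The brightest 461 loci, ranked on arrays of other slides, exceeded the dimmest 461 by 0.58 and 0.68 on the log2 scale, against 2.93 to 3.20 elsewhere.

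**Figure D3:**
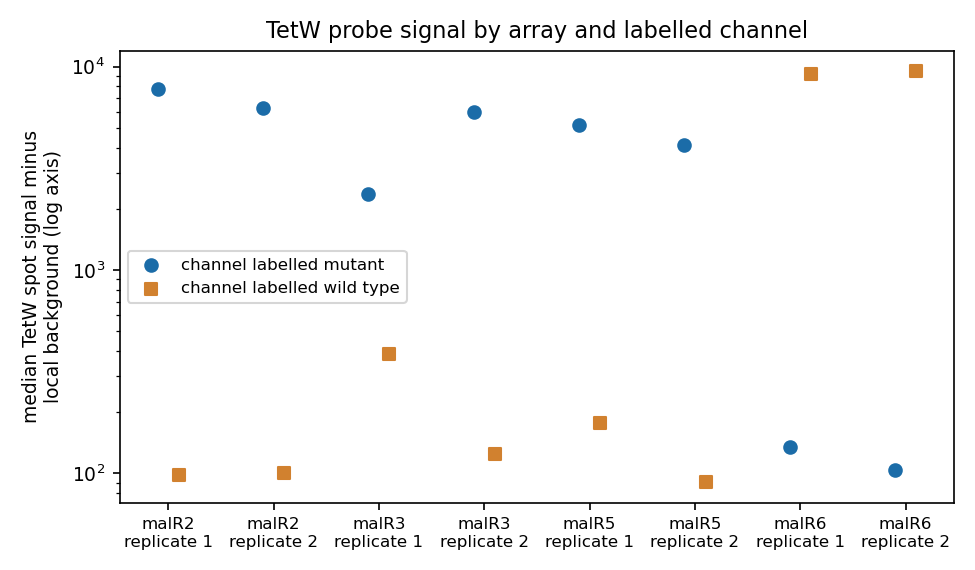
Median background-subtracted signal of 32 TetW spots (y axis, log scale) on each array (x axis), in the channel labelled mutant (circles) and the channel labelled wild type (squares). The mutant channel is brighter on the 6 malR2, malR3 and malR5 arrays and the wild type channel on both malR6 arrays.

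**Figure D4:**
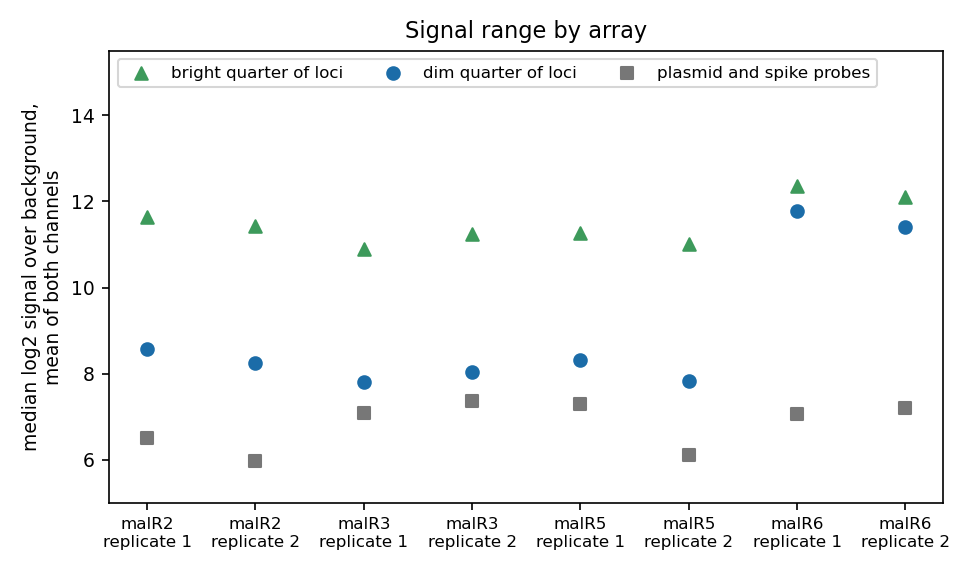
Median log2 signal over background, averaged over both channels (y axis), on each array (x axis), for the brightest 461 loci and the dimmest 461 loci, ranked on arrays of other slides, and 23 names of plasmid and spike probes. On the malR6 arrays the dimmest loci lie 4.72 and 4.20 above the plasmid and spike probes.

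The mutants were also compared with one another, by tests of the difference at each locus. The region Bbr_0116 to Bbr_0123 differed in all 8 loci between the malR3 mutant and both the malR2 mutant (median difference -3.51, malR2 minus malR3) and the malR5 mutant (3.85, malR3 minus malR5). Of its 8 loci, 5 also differed between the malR2 and malR5 mutants, by a median of 0.42. By contrast 0 of 4 loci of Bbr_1655 to Bbr_1658 and 0 of 4 of Bbr_1891 to Bbr_1894 differed between the malR2 and malR5 mutants, with median differences of -0.30 and 0.63 on the log2 scale; this does not show that they were alike. Only 2 loci differed by over 3-fold between these mutants, although 841 differed at the adjusted threshold. The other pairs differed in 986 loci (malR2 and malR3), 1225 (malR2 and malR6), 1224 (malR3 and malR5), 1252 (malR3 and malR6) and 1143 (malR5 and malR6), with malR6 as labelled; slide and mutant cannot be told apart except within slide 1.

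Calls over 3-fold were shared by the malR2 and malR5 mutants at 24 rising loci, where 0.339 would be expected of independent calls (Fisher's exact test, adjusted p = 1.19e-51), and at 15 falling loci, where 0.130 would be (adjusted p = 1.38e-35). This test counts each locus as independent, although 36 of 41 such loci in malR2 and 34 of 40 in malR5 lay in runs of neighbours. Its p-values are therefore too small. The ratios of these mutants had r = 0.86 and rho = 0.23 across loci, which are not independent replicates, and a covariance of 0.327. Simulated ratios with no change, sharing only the spread between arrays of 1 wild type, gave r = 0.50 and a covariance of 0.00189. That r was fixed by the simulation, which gave mutant and wild type the same spread. The simulation held no difference between wild type extracts, so it sets no limit on what a shared wild type extract adds. At the adjusted threshold 45 loci were higher and 33 lower in all 4 mutants, against 16.6 and 14.7 expected, with malR6 as labelled. With median centring the numbers were 19 and 12, below the 25.6 and 16.2 then expected, so that the excess does not hold in that setting; without a dye effect they were 32 and 17, against 7.75 and 6.94. A further 33 and 38 were called alike in the malR2, malR3 and malR5 mutants and in the opposite direction on the malR6 arrays. Part of any overlap can come from shared wild type RNA and the shared dye estimate.

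Neighbouring loci changed together. Of the 41 loci over 3-fold in the malR2 mutant 36 lay in 6 runs, as did 34 of 40 in the malR5 mutant, where shuffled calls gave means of 0.0488 and 0.0445 loci (one-sided permutation test, p = 0.0001, the smallest that 10000 shuffles can give). Runs held 638 of the called loci in the malR2 mutant, 620 in malR3, 795 in malR5 and 858 on the malR6 arrays, against shuffled means of 329, 433, 440 and 465 (p = 0.0001 in each, permutation test). The 2 loci over 3-fold in the malR3 mutant are too few for a run of such loci, and 0 of the 8 on the malR6 arrays lay in one. Both loci of the malR3 mutant lay in runs of called loci, Bbr_0366 in that from Bbr_0365 to Bbr_0371 and Bbr_1898 in that from Bbr_1896 to Bbr_1898, as did 6 of the 8 on the malR6 arrays, where 858 of all 1190 called loci did.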

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

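All tests that weigh an explanation in this part were chosen after the result was seen, except that of unspecific hybridisation, for which the ranking of loci was revised afterwards; the opposite calls come from tests planned beforehand, in regions picked afterwards.

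TetW lies outside the loci compared, and its probes gave log2 ratios of 6.42 in the malR2, 5.83 in the malR3 and 6.21 in the malR5 comparison but -2.41 on the malR6 arrays as labelled. The size of the last value depends on the background correction. In the channel labelled mutant TetW signals were 135 and 104, below the fitted backgrounds of 1548 and 720. Before that correction the channel labelled wild type was 67.9 and 91.2 times brighter. An admixture of malR6 mutant RNA in the wild type extract is argued against, since it would leave at least as much TetW in the mutant channel of each array, whereas the ratios were -2.76 and -2.05 on the 2 arrays (fitted -2.41, SE 0.16). Channels named the wrong way round were examined through correlations of gene levels. The channel labelled malR6 mutant correlated better with the other slides' wild type channels than the channel labelled wild type did, by 0.0820 and 0.108. On the other 6 arrays the mutant channel correlated less well. But the channel labelled malR6 mutant also correlated better with the other slides' mutant channels. On malR6 replicate 1, r with the mutant channel of malR3 replicate 1 was 0.78, against 0.66 for the channel labelled wild type. The comparison therefore cannot tell swapped names from a channel that correlates less well with all others. Swapped names stay open as a hypothesis. Neither a wild type that itself carried the marker nor RNA of another strain in the wild type extract was tested. Either alone would leave TetW signal in the channel labelled mutant, if the malR6 mutant carried TetW. There the signals were 135 and 104, against 2354 to 7742.5 in the mutant channels of the other arrays. The wild type channels of those arrays had 90.5 to 385. Under that condition these values argue against either as the sole cause.

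The malR2 and malR5 mutants shared 39 loci over 3-fold, including Bbr_1655 to Bbr_1658 and Bbr_1891 to Bbr_1894. Unusual wild type RNA on their common slide is argued against as the whole cause, because the mutant channels of slide 1 differed from the wild type of slide 2 by a median of 2.26 in the direction of the change, against a median change of 2.61. But the wild type of slide 1 also differed from that of slide 2, by a median of -0.65 in that direction. At 29 of the 39 loci it lay opposite to the change. Bbr_1894 was at 14.5 in the slide 1 wild type and 12.2 in the slide 2 wild type. Part of the change, and of the deepest falls, can therefore come from the wild type. A single mutant extract hybridised under both names stays open. In both dye orientations 7 loci, among them Bbr_0114 and Bbr_1898, differed by more than the largest difference of a plasmid or spike probe (1.24 on the log2 scale). But these are the extremes of 1843 loci, set against only 20 plasmid and spike names. Over all loci the malR2 minus malR5 differences had r = 0.96 between the dye orientations. The mutant channels of malR2 and malR5 differed with an SD of 0.25 over loci, against 0.12 between their wild type channels. Differences that repeat in this way go against a single extract, but the plasmid and spike probes repeated theirs too. Of those names 4 differed by over 2-fold in both orientations, as did 15 of the loci. These comparisons therefore cannot decide. A common response of both mutants may remain, as a hypothesis found and tested on the same data.

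Gene signals on the malR6 arrays spanned a narrow range, which moves with each malR6 value given. Saturation is argued against by 0 saturated spots. Unspecific hybridisation or high background is argued against because the dimmest loci lay further above plasmid and spike probes than on any other array, by at least 1.91 on the log2 scale. Genomic DNA labelled with the RNA stays open, because the gap between bright and dim loci, at most 0.232 of the smallest gap elsewhere, only restates the narrow range. No biological explanation was tested for it, and the slide holds malR6 arrays alone.

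Loci called in opposite directions, whose differences were all called too, numbered 223 between the malR2 and malR3 mutants (311 expected of independent calls), 269 between malR2 and malR5 (312), 391 between malR2 and malR6 (323), 366 between malR3 and malR5 (358), 389 between malR3 and malR6 (371) and 299 between malR5 and malR6 (373), with malR6 as labelled. The excess was not tested, and 3 of the 6 counts lie below the number expected. That the differences were all called adds no support, since calls on opposite sides of 0 in the same model nearly imply it. With the malR6 channels turned, the opposite calls would number 269 with malR2 (322 expected), 375 with malR3 (370) and 457 with malR5 (371). Bbr_0116 to Bbr_0123 differed in all 8 loci by a median of -3.51 (malR2 minus malR3) and 3.85 (malR3 minus malR5). Part of these differences can come from the wild type, which lay lower there on slide 2 than on slide 1 (Bbr_0118 at 11.7 against 13.2). Bbr_0106 to Bbr_0109 differed in all 4 loci by a median of 2.60 (malR2 minus malR6) and 2.48 (malR5 minus malR6), which rests on the malR6 labels; with the channels turned the malR6 mean would be 1.04, beside 1.43 and 1.31, and the medians 0.26 and 0.073, which were not tested.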

How the results depend on the processing

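The settings without the malR6 arrays, with slide 1 alone, and with neither background correction nor loess (median centring only) were chosen after seeing the data; the others were planned. Of 344 alternative values of counts, 302 stayed within 1.5 times, 7 were higher and 35 lower by more. Of 2928 alternative values for the 139 pairs of a locus and a mutant under the rule for single loci, 2779 kept their call, 139 were no longer called and 10 reversed. These tallies are not shares of independent checks. No filter on dim loci equals the main setting, and another dye term or leaving out another mutant's array leaves the ratio itself unchanged. With neither background correction nor loess 102 of the 139 pairs kept their call, 32 lost it and 5 reversed. The mean changes of Bbr_1655 to Bbr_1658, Bbr_1891 to Bbr_1894 and Bbr_0116 to Bbr_0123 in the malR2 and malR5 mutants kept their direction under each signal and scaling setting.

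Calls in the malR2 mutant numbered 645 on its own arrays and 533 by Cyber-T at its p threshold without a fold threshold; calls in the malR3 mutant 624 by Cyber-T and 678 with neither correction. The malR5 mutant had 647 on its own arrays, 535 by Cyber-T and 420 with neither correction. The malR6 arrays gave 774 with processed signals, 782 with the series table, 777 on their own, 674 by Cyber-T and 524 with neither correction; the share higher, as labelled, moved from 47.9% to 60.3% with processed signals and 67.9% with neither correction (52.1%, 39.7% and 32.1% with the channels turned). Over 3-fold the malR3 mutant had 1 locus without background correction, 1 with neither correction, 20 with processed signals and 19 with the series table, and the malR6 arrays had 2 without background correction, 2 with processed signals, 2 with the series table, 96 with median centring and 65 with neither correction. The background fitted by normexp averaged 720 to 5493 on malR6 channels and 38.2 to 277 elsewhere. On the malR6 arrays the measured local background was 34 to 39.5, and 8.47% to 27.6% of spots lay below the fitted mean. The malR6 ratios of the main setting therefore rest on a fitted background far above the measured one. Without background correction Bbr_0433 was at -2.59 in place of -4.84. Beyond that the cause was not tested.

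The malR2 and malR5 mutants differed in 1327 loci with a dye effect per slide and, with the same value, on slide 1 alone; with neither correction 228 loci differed between malR2 and malR3 and 390 between malR5 and malR6. Shared calls moved with median centring to 768 (malR2 and malR3), 294 (malR2 and malR5) and 31 (all 4 mutants), and without a dye effect to 49 (all 4). The cause was not tested.

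Leaving out each array in turn, with a lone array assumed to vary like the others, gave 323 to 1188 calls in the malR2 mutant, 1015 to 1162 in malR3, 449 to 1338 in malR5 and 743 to 1348 for malR6, and over 3-fold 40 to 41, 2 to 3, 39 to 40 and 5 to 11. Differing loci ranged from 590 to 1077 (malR2 and malR3), 319 to 1092 (malR2 and malR5), 840 to 1418 (malR2 and malR6), 813 to 1280 (malR3 and malR5), 1010 to 1298 (malR3 and malR6) and 770 to 1346 (malR5 and malR6).

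Reversed values under median centring were 0.020 for Bbr_0451 and -0.048 for Bbr_1040 in the malR2 mutant, -0.017 for Bbr_1443 in the malR5 mutant, and -0.14 for Bbr_0894 and 0.14 for Bbr_0030 on the malR6 arrays. With neither correction they were 0.13 for Bbr_0451, -0.16 for Bbr_1040 and -0.020 for Bbr_1875 in the malR2 mutant, -0.066 for Bbr_1443 in the malR5 mutant and 0.072 for Bbr_0030 on the malR6 arrays. The cause was not tested. No paired analysis was possible because each array already holds the mutant with its own wild type. The lists planned for set tests could not be built, so their alternatives were not run. Signal over background limited dim loci most on the malR3 arrays, where 65 loci were above background on neither array in at least 1 strain, 6 of them in neither strain; 17 of the 65 have a fold that is a lower bound.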

Other observations

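None of the values here comes from a test planned beforehand, except the calls themselves. Loci with the LacI-type sugar-binding motif numbered 7, and their called changes ran in both directions. Bbr_0122, inside the region Bbr_0116 to Bbr_0123, was called at -0.45 in the malR2 mutant, 0.44 in malR3 and -0.83 in malR5. Bbr_0023 was called at 0.77 in the malR2 mutant, 0.18 in malR3, -0.14 in malR5 and -0.60 on the malR6 arrays as labelled; median centring ended the last 2 of these calls, at -0.15 (adjusted p = 0.160) and -0.20 (adjusted p = 0.0694). Of the other loci with the alpha-amylase motif, Bbr_1564 was called at 0.55 in the malR3 mutant, -0.14 in malR2, -0.13 in malR5 and 0.34 for malR6, and Bbr_1298 at -0.23 in malR2, -0.28 in malR3, -0.16 in malR5 and 0.14 for malR6. Bbr_0111 was called at 0.24 in malR2, -0.14 in malR5 and -0.70 for malR6, and Bbr_1833 at -0.41 in malR5 alone of the 4. With neither background correction nor loess, a setting chosen after seeing the data, Bbr_1564 was at 0.019 in malR5 and was no longer called in malR3 (0.28). Bbr_1890, with an ABC transporter ATPase motif, was called at -0.99 in the malR3 mutant, 0.27 in malR5 and -0.74 for malR6, where median centring turned it to 1.45. At least 1 other signal or scaling setting also ended the calls of Bbr_0023 in malR3, Bbr_1564 in malR2 and malR5, Bbr_1298 in malR5 and for malR6, Bbr_0111 in malR2 and malR5, and Bbr_1890 in malR5. Plasmid and spike probes ran from -0.80 to 0.016 in malR2, -0.31 to -0.15 in malR3, 0.24 to 0.52 in malR5 and 0.016 to 0.18 for malR6. Called values of this size are therefore not by themselves evidence of a change. For malR6 the background correction holds that range narrow, so it sets no scale for larger values there.

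Probes named for 16S ribosomal RNA, outside the loci compared, were at -2.02 in the malR2 mutant (adjusted p = 0.000697), 0.91 in the malR3 mutant (adjusted p = 0.00821) and 0.71 on the malR6 arrays as labelled (adjusted p = 0.0200). In the malR5 mutant, on the same slide as malR2, they were at -0.24 (adjusted p = 0.306); that difference was not tested.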
